A study of Arabidopsis thaliana with 24 samples.

How the data were processed

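The series measured total RNA from whole leaf explants of Arabidopsis thaliana. Per the labels' protocols, seedlings of Col-0 (WT) and coi1-2 grew for 12 d in days of 16 h light and nights of 8 h, at 22 °C, on MS medium that held 1% sucrose. The first pair of rosette leaves was detached at the base of the blade and cultured on B5 medium without sucrose at 22 °C under 24 h light, and explants were frozen at t0, after 10 and 30 min, and after 1, 2, 4, 8 and 12 h. Libraries were sequenced on the HiSeq platform. Per the submitters' processing notes, the authors used Trim Galore 0.5.0, STAR 2.7.2b and RSEM 1.3.2 with the build TAIR10, and neither parameters nor the annotation version, strand setting or filters were stated. The deposited values are TPM per gene, 1 column per library, in 1 table for WT and 1 for coi1 with 37686 loci each. Every column used sums to 1000000 within rounding to 2 decimals, so TPM keeps no trace of depth, and the precision from counting is unknown.

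The 24 columns whose genotype, time and replicate number matched a sample label were used. Another 8 columns of the WT table, with replicate number 2, matched no label in this series and were not used in any step. Gene names came from a TAIR10.1 annotation, in which 37390 of the 37686 loci were found. It was used for names only, and no coordinates are given.

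All fits were made in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), with empirical Bayes moderation with a trend, on genes with at least 1 TPM in at least 2 libraries of the fit. A gene was called at an adjusted p (Benjamini-Hochberg over the genes tested) below 0.05. The coi1 times were compared with t0 in 1 fit of 16 libraries in 8 time groups, with 8 residual degrees of freedom shared across times. This takes the spread of a gene to be the same at all times. The replicate pairs differed by a root mean square of 0.691 log2 units at t0 and 1.039 at 30 min, against 0.319 to 0.501 elsewhere. As t0 enters every comparison, the p-values may be too small, most of all at 30 min. The WT time course was an F test of a natural spline with 3 degrees of freedom in the order of the times (splines 4.3.3), with 4 residual degrees of freedom. Genotype was the coi1 minus WT coefficient of an additive model of genotype and time over 24 libraries, with 15 residual degrees of freedom, and the difference in time course was an F test of the 3 terms of genotype by spline, with 16. Changes in WT at single times had 1 library on each side and no test.

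The 29 gene lists, with 353 memberships of 351 loci, were fixed by symbol, and 335 of the memberships had their symbol in the reference while 18 rested on the locus alone. They covered jasmonate biosynthesis, JAZ repressors, jasmonate response and turnover, rapid wound and stress transcription factors, WIND factors, touch, auxin and tryptophan biosynthesis, auxin response, root founder and root stem cell regulators, age-related SPL factors, ethylene, abscisic acid, salicylic acid, photosynthesis, morning and evening clock, sugar starvation, cell cycle, ribosome biogenesis, heat shock, glucosinolate, anthocyanin and flavonoid, markers of guard cell, trichome, epidermis, vascular, root and shoot meristem tissue, and reference genes. The 26 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 182 lists and times in coi1 and over 26 lists for genotype. For genotype an exact two-sided sign-flip test of the list mean over the 8 times was added. In WT a list's median change was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Their genes were drawn one by one, so the percentiles do not allow for genes of a list that vary together. Lists at coi1 times and lists by genotype each form 1 family of tests.

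Genes were named by a rule: COI1; the 10 highest and 10 lowest genotype differences past the threshold with a mean of at least 5 TPM in either genotype; the 20 smallest p of the time-course test with a largest group mean of at least 10 TPM; the 6 highest and 6 lowest changes at 30 min, 2 h and 12 h with at least 10 TPM, past the threshold in coi1 and as single-library values in WT; up to 4 members of each list with the largest changes; and ERF109, ASA1, VSP2, LOX2, JAZ10 and WOX11. Organelle genes and genes with no protein-coding annotation were skipped. Groups, comparisons, lists, this rule and the first set of alternatives were chosen before the data were examined. Members beyond the 4 per list are named in places to complete a pathway, and these were chosen after their values were seen. The value of 1 list member is not reported here.

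The alternatives were a pseudocount of 0.1, no filter and a filter of 5 TPM, TPM rescaled by median-of-ratios factors over genes of at least 5 TPM, moderation without trend, replicate number as a block, only the 4 libraries compared, 1 coi1 replicate number alone, the 16 group means, a spline with 2 degrees of freedom, time as a factor, an estimated correlation, and each library left out in turn. Alternatives without the 2 h time, without the 2 h and 30 min times, and with libraries left out of the list tests were added after the data were seen. Where a library left out leaves 1 in its group, that library is assumed to vary like the other groups.

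The fits were tested on simulated data of the same layout with 200 changed genes (seed 1). The coi1 comparison recovered 55.2%, 79.1% and 97.0% of changes of 2-, 4- and 8-fold with 8 false calls among 19323 genes. The genotype comparison recovered 94.0%, 97.0% and 98.5% with 11 false calls among 19757 genes, the time-course difference 9.0%, 41.8% and 69.7%, and the WT spline 0%, 0% and 21.2%. These rates and false calls describe the simulated genes only. Whether they hold for transient changes, for genes of low abundance or for genes that vary together was not tested. A raised list was called by camera, and none of 25 others was. These were random lists of independent genes, so the test does not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3.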

Results

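RNA abundance was measured by sequencing in detached leaf blades of Arabidopsis thaliana, the explants from which roots regenerate. Leaves of the wild type Col-0 (WT) and of coi1-2, a mutant in the jasmonate receptor gene COI1, were collected at detachment (t0), after 10 and 30 min, and after 1, 2, 4, 8 and 12 h. The 24 libraries comprised 8 WT libraries, 1 at each time, and 16 coi1 libraries, 2 at each time. All values are TPM, transcript abundances scaled to the same total in each library. The read depth is therefore unknown, and no counting interval can be given. Between 17019 and 17840 genes reached 1 TPM in a library, and the 10 most abundant genes held from 8.9% to 14.2% of the TPM. WT values at single times have no replicate, and changes in WT are given as log2 differences between 1 library and 1 library without a p-value. Time after detachment was confounded with time of day, transfer to medium without sucrose and continuous light, and WT and coi1 values came from separate tables. The p-values measure only the spread between these samples, since the replicates were not stated to be separate cultures. For the coi1 times they take this spread to be equal at all times. The t0 and 30 min pairs spread more, so these p-values may be too small.

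COI1 (AT2G39940) itself did not differ detectably between the genotypes. Its abundance was 17.2 ± 6.31 TPM in WT (SD, n = 8 libraries over all times) and 17.3 ± 3.55 TPM in coi1 (SD, n = 16), a log2 difference of 0.07 ± 0.11 (SE; adjusted p = 0.737). In coi1 the transcript rose at 8 h (log2 0.58 ± 0.11, adjusted p = 0.00701) and at 12 h (0.64 ± 0.11, adjusted p = 0.0028), and the WT values at these times were 0.52 and 0.60. The coi1-2 allele carries a substitution in the protein, so the transcript level does not check the genotype labels.

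The coi1 time course asked which early responses to detachment took place without full jasmonate perception. At 10 min, 3 of the 24 measured genes for rapid wound and stress transcription factors rose and none fell, and 17 rose when adjusted over the list alone, with a median log2 change of 3.45. ERF109 (AT4G34410) rose from 0.34 to 39.7 TPM, and ERF5 and CBF2 rose by log2 3.96 and 5.05. The abscisic acid gene NCED3 and the ethylene gene ACS6 rose by 3.42 and 4.19, and among jasmonate response genes ORA47 and CYP94B3 rose by 4.78 and 2.38. ACT2, a reference gene, fell by 0.83, and no reference gene fell after rescaling. The wound list differed from other genes (camera adjusted p = 2.82e-21, or 0.416 with an estimated correlation). Its size rested on the t0 libraries: the median was 4.90 with 16 genes rising when coi1 t0 replicate 1 was left out, and 1.52 with 3 rising when coi1 t0 replicate 2 was left out.

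At 30 min in coi1, AT2G17660 rose from 0.94 to 97.2 TPM (log2 5.80 ± 0.38), and the cell wall gene XTH18 (AT4G30280), the EXORDIUM-like gene PHI-1 (AT1G35140), AT3G01830, AT1G56660 and SRO5 (AT5G62520) rose by 4.50 to 5.29. BT2 (AT3G48360) fell from 184 to 7.66 TPM, and RVE2, AT1G23390, AT5G21940 and the locus pair AT14A fell by 3.56 to 3.69. The AT14A pair (AT3G28290 and AT3G28300) had identical values in every library, so its 2 loci were not resolved. Among auxin response genes 5 of 16 rose and none fell, or 6 and none adjusted over the list alone, with IAA6, IAA3 and IAA19 at 2.07, 1.75 and 1.73. Among JAZ repressor genes, which encode the proteins that jasmonate perception removes, 3 of 10 rose, or 5 adjusted over the list alone, led by JAZ5 (2.63) and JAZ6 (2.49). SPL3 and SPL9 fell by 1.17 and 1.02, and neither was called after rescaling. The auxin response list (median 0.37) and the JAZ list (median 0.71) had camera adjusted p of 0.00065 and 0.000329, or 0.46 and 0.416 with an estimated correlation. With 1 t0 or 30 min library left out the medians ranged from 0.09 to 0.62 and from 0.25 to 0.66, and both lists stayed called. The wound list had 2 genes rising (2 adjusted over the list alone) and a median of 1.04, which was -0.07 without coi1 t0 replicate 2 (adjusted p = 0.403) and 0.05 without coi1 30 min replicate 1 (adjusted p = 0.0682). The call of AT14A ended under 7 of its 11 alternatives, and those of XTH18, AT3G01830, BT2, RVE2 and PHI-1 ended without coi1 t0 replicate 2. None of the 12 loci was called when only the 4 libraries compared were fitted.

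At 1 h, jasmonate genes rose in coi1 as well. JAZ9, AOC3, JOX2, CYP94C1 and JAZ6 rose by 5.24, 5.03, 4.63, 4.32 and 4.26, and JAZ10 (AT5G13220) rose from 1.59 to 5.54 TPM (log2 1.31). By list, 8 of 10 JAZ genes, 7 of 14 jasmonate biosynthesis genes and 6 of 15 jasmonate response genes rose, and 1 response gene fell. Adjusted over the list alone, 8, 8 and 8 rose and 1 response gene fell. Ribosome biogenesis genes moved the other way, with 10 of 12 falling by either adjustment and FIB2 and NOP56 falling by 2.14 and 1.90. At 4 h, 6 ribosome biogenesis genes rose, or 10 adjusted over the list alone, among them FIB2 (1.98) and NOP56 (1.32). The camera adjusted p was 1.49e-07 for JAZ (0.255 with an estimated correlation), 0.000154 for biosynthesis (0.669), 0.000346 for response (0.416), and 0.00141 and 0.000118 for ribosome biogenesis at 1 h and 4 h (0.754 and 0.699).

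At 2 h in coi1 GPT2 (AT1G61800), a plastid glucose 6-phosphate transporter gene, rose from 0.70 to 149 TPM, and GBSS1 (AT1G32900), a granule-bound starch synthase gene, rose from 1.64 to 244 TPM. AT2G43620, the pirin gene PRN, XTH24 and LEA3 rose by 5.37 to 6.10. AT2G33830, a dormancy-associated gene, fell from 802 to 4.60 TPM, BT2, EXPA8, RVE2 and AT14A fell by 5.51 to 5.73, and WIND2 fell by 2.05. The calls of GBSS1 and LEA3 ended without coi1 t0 replicate 2 and without coi1 2 h replicate 1, and that of AT2G33830 without the latter.

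By 12 h in coi1 CHS (AT5G13930) rose from 3.72 to 1889 TPM, F3H (AT3G51240) from 1.25 to 811 TPM, and the regulators PAP1 (AT1G56650) and PAP2 (AT1G66390) by 7.43 and 7.87. GASA6 (AT1G74670), a gibberellin-stimulated gene, fell from 584 to 0.1 TPM, and AT3G15450, AT5G18600, EXPA8 and LHB1B1 fell by 5.12 to 6.39. In the anthocyanin and flavonoid list 11 of 12 genes rose, or 12 adjusted over the list alone (median 4.15, adjusted p = 9.02e-12, or 0.255 with an estimated correlation). In the glucosinolate list 12 of 17 rose, or 15 adjusted over the list alone, with BCAT4, CYP79F1 and MAM1 up by 5.29, 5.13 and 4.57 (median 2.28, adjusted p = 3.31e-09, or 0.416). Photosynthesis genes fell in 14 of 20 cases by either adjustment, with LHCB3 and LHCA4 falling by 3.01 and 2.93 (median -1.06, adjusted p = 2e-10, or 0.416). Of 8 sugar starvation genes, 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (5 and 0 after rescaling), with DIN10 and TPS9 falling by 4.56 and 3.04 (median -2.82, adjusted p = 2.78e-05, or 0.208). At 8 h the same 4 lists had moved the same way, with medians of 2.13, 1.98, -0.78 and -2.56.

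Morning clock genes rose in coi1 at 1 h, 2 h and 4 h. Of 8 genes, 5 rose at 2 h and 3 at 4 h by either adjustment. The camera adjusted p was 0.00927 at 2 h and 0.0152 at 4 h, or 0.699 and 0.7125 with an estimated correlation. At 1 h, 5 of 8 morning genes rose, or 6 adjusted over the list alone, with CCA1, PRR9 and LNK2 up by 5.72, 5.45 and 4.28, and 1 evening gene fell (morning median 2.95, adjusted p = 0.000693, or 0.583 with an estimated correlation; evening median -2.7, adjusted p = 0.467). At 30 min the replicates parted: the morning median was 4.90 without replicate 1 and 0.10 without replicate 2, and the evening median was -4.18 and 0.47. Photosynthesis genes rose in 10 of 20 cases at 1 h and 1 fell, by either adjustment (adjusted p = 0.00069, or 0.699), and LHCB2.1 rose by 4.03 at 4 h.

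WOX11 stayed at or below 0.22 TPM in all 24 libraries, no shoot meristem marker reached the expression filter, and of 9 root tissue markers 2 were measured: NRT2.1 rose at 1 h, 8 h and 12 h (2.59 at 12 h) and CASP1 fell at 1 h and 2 h by 0.79 and 0.73. Of 7 root founder genes, 2 fell at 12 h, or 2 adjusted over the list alone, and none rose (median 0.31, adjusted p = 0.849). WIND1 fell at 8 h and 12 h by 0.85 and 1.12. At 1 h no cell cycle gene rose and 7 of 22 fell, or 7 adjusted over the list alone, and after rescaling 1 rose and 3 fell. The cell cycle list was called lower at 30 min (median -0.42, adjusted p = 0.0254, or 0.809 with an estimated correlation), 4 h (0.00779, or 0.754) and 8 h (0.0478, or 0.813), and each call ended without coi1 t0 replicate 2 or coi1 30 min replicate 1. Guard cell markers rose in 3 of 5 cases at 2 h, trichome markers in 2 of 5 at 12 h, epidermis markers in 2 of 3 at 1 h (adjusted p = 0.0396, or 0.46, and 0.0909 after rescaling; CER1 rose by 4.63 at 2 h), and vascular markers fell in 3 of 9 at 1 h, the same counts adjusted over each list alone. Of 6 SPL genes 3 rose and 1 fell at 12 h by either adjustment, or 1 and 1 after rescaling. Salicylic acid genes rose in 5 of 14 cases at 12 h and 1 fell by either adjustment, and PR5 rose by 3.67 at 8 h. Heat shock genes rose in 4 of 9 cases and ethylene genes in 3 of 9 at 2 h, the same adjusted over each list alone, and abscisic acid genes rose in 2 of 15 at 1 h, or 1 adjusted over the list alone. Camera did not call guard cell (adjusted p = 0.177), trichome (0.109), vascular (0.469), SPL (0.652) or salicylic acid genes (0.584) at those times. Nor did it call heat shock (0.338) or ethylene genes (0.3125). It called abscisic acid genes (0.0478, or 0.832 with an estimated correlation, and 0.155 after rescaling). At 1 h 2 heat shock genes rose and 3 fell, and of all 19323 genes 2069 rose and 3969 fell. Auxin and tryptophan biosynthesis genes rose in 6 of 15 cases at 12 h and 2 fell, or 8 and 2 adjusted over the list alone (adjusted p = 0.212). The 3 touch genes had medians of 2.06 at 10 min and 3.17 at 30 min, with none called by either adjustment. Without coi1 t0 replicate 2 these medians were -1.06 and 0.04. The touch list was called at both times (camera adjusted p = 0.0282 and 0.0223, or 0.669 and 0.668 with an estimated correlation). These calls ended without that t0 library, without either coi1 30 min replicate and after rescaling. GAPC1 and UBQ10, both reference genes, rose by 1.22 and 1.06 at 12 h (1 of them after rescaling), and the reference list median of -0.13 at 30 min and at 1 h became 0.07 and 0.05 after rescaling.

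Of the 182 tests of 26 lists at 7 times, 59 passed adjusted p 0.05, and none did with an estimated correlation, where the lowest adjusted p was 0.137 for sugar starvation at 8 h. Only t0 and 30 min libraries were left out of the list tests. A call at another time was therefore not tried without a library of that time. Of the 59 calls, 31 were kept after rescaling and without each of coi1 t0 replicate 1, t0 replicate 2, 30 min replicate 1 and 30 min replicate 2. These were jasmonate response, wound, photosynthesis and ribosome biogenesis at 10 min; JAZ and auxin response at 30 min; the 3 jasmonate lists, photosynthesis, morning clock, ribosome biogenesis and glucosinolate at 1 h; JAZ, morning clock, starvation and glucosinolate at 2 h and 4 h, with ribosome biogenesis at 4 h; photosynthesis, starvation, glucosinolate and anthocyanin at 8 h and 12 h, with JAZ at 12 h. From 2 h to 12 h the wound list was not called, with medians of -0.24 to -0.49, and its direction followed the t0 library. Without coi1 t0 replicate 1 its medians were 0.72 to 1.39 with 4 or 5 genes rising, and without coi1 t0 replicate 2 they were -1.81 to -2.04 with 8 to 12 genes falling, all called. The camera test was up where the median was just below 0 for glucosinolate at 10 min (median -0.04, mean 0.22) and ethylene at 30 min (median -0.05, mean 0.65), and in no other called list; among uncalled lists they parted too, as for salicylic acid at 1 h (median -0.52, test up).

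**Figure D1:**
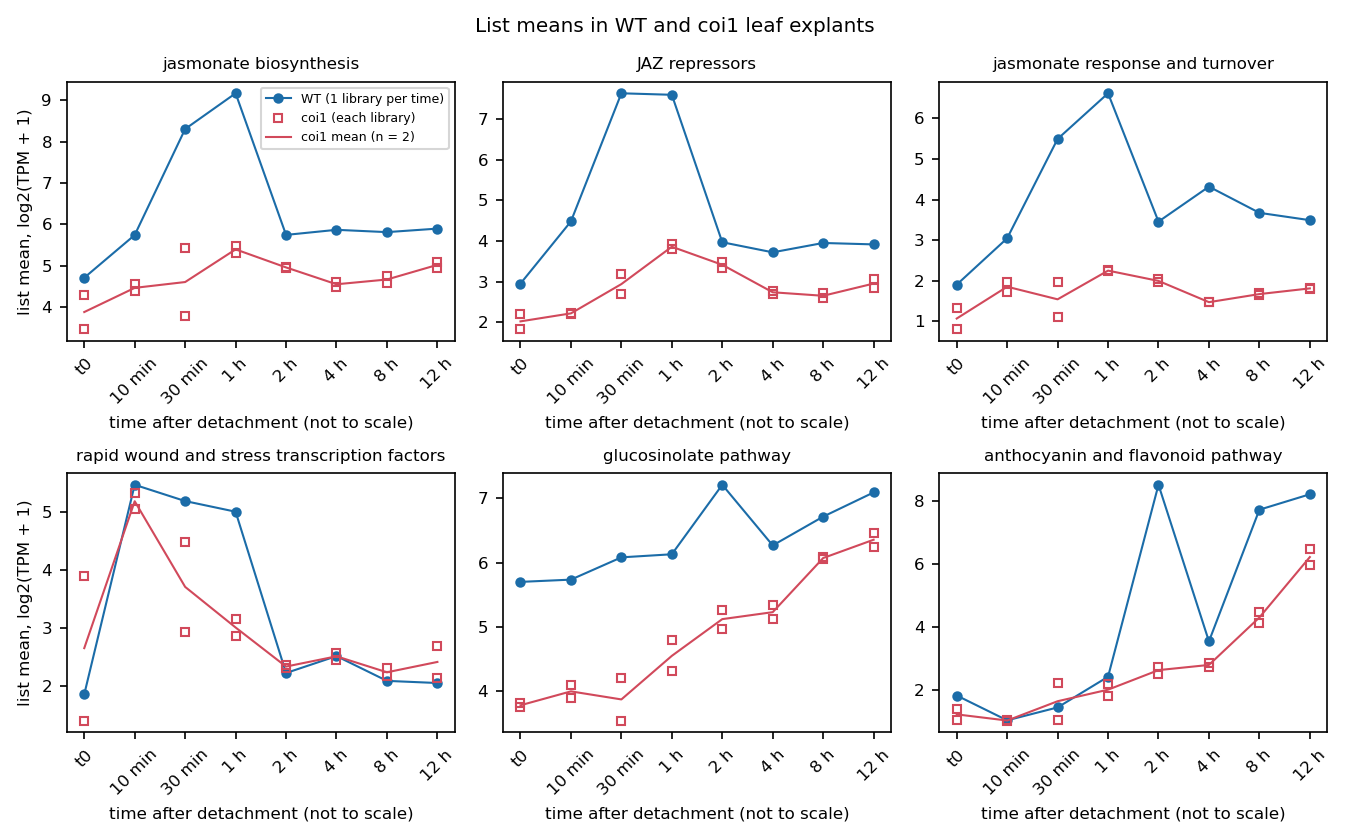
Mean log2(TPM + 1) of 6 gene lists (y axis) against time after detachment (x axis, not to scale) in WT (filled circles, 1 library per time) and coi1 (open squares, each library; line, mean of 2). The JAZ mean in coi1 lies below WT by 4.69 at 30 min, and the 2 coi1 t0 libraries lie at 3.90 and 1.41 for wound genes.

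With limma, 103 genes changed in coi1 at 10 min (70 higher, 33 lower), 1784 at 30 min (534 and 1250), 6038 at 1 h (2069 and 3969), 4941 at 2 h (2552 and 2389), 2708 at 4 h (1428 and 1280), 2824 at 8 h (2112 and 712) and 4185 at 12 h (3001 and 1184), of 19323 tested. The share of higher genes depended on scaling. After rescaling by median-of-ratios factors it went from 68.0% to 80.2% at 10 min, 29.9% to 61.8% at 30 min (1167 genes), 34.3% to 50.8% at 1 h, 74.8% to 59.7% at 8 h and 71.7% to 57.3% at 12 h. The median change of all genes was -0.18 at 30 min, -0.17 at 1 h and 0.11 at 8 h before rescaling and -0.01, -0.02 and 0.00 after it. Single libraries moved the counts. At 10 min the count was 372 without t0 replicate 1, 226 without t0 replicate 2, and 26 and 45 without 10 min replicates 1 and 2. At 30 min it was 140 without t0 replicate 2 and 7894 without 30 min replicate 1. At 1 h it was 3222 without t0 replicate 2 and 2965 without 1 h replicate 1, and at 2 h it was 2221 and 3151 without 2 h replicates 1 and 2. At 4 h it was 1397 without t0 replicate 1 and 698 and 771 without 4 h replicates 1 and 2. At 8 h it was 1818 without t0 replicate 1 and 1467 and 1751 without 8 h replicates 1 and 2, and at 12 h it was 2674 and 1931 without 12 h replicates 1 and 2. With only the 4 libraries compared, no gene was called at 10 min or 30 min, where limma over all 16 libraries had 2209 and 5794 genes at an unadjusted p below 0.05. That fit called 2967 genes at 1 h, 4560 at 4 h and 1595 at 8 h.

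**Figure D2:**
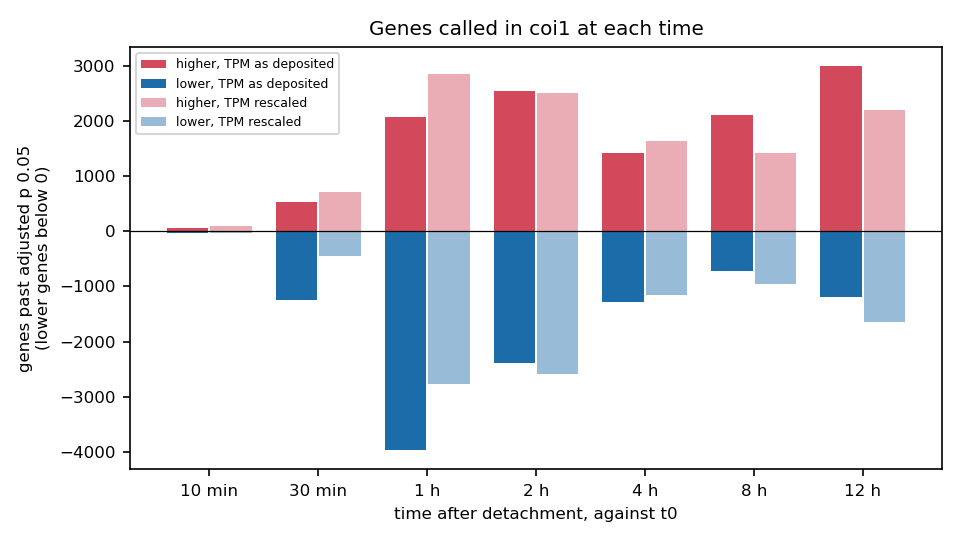
Number of genes past adjusted p 0.05 in coi1 (y axis; lower genes below 0) at each time against t0 (x axis), for TPM as deposited and after rescaling. At 30 min the higher share is 29.9% before and 61.8% after rescaling.

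The WT time course asked how leaves with a working COI1 responded to detachment. At 30 min ERF109 had gone from 0.03 to 437 TPM, and AT4G27654, AOC3, AT3G01830, CML38 and AT2G22880 were higher by log2 7.52 to 8.28. The auxin-regulated gene AT4G38860 (SAUR16) went from 51.2 to 0.92 TPM, and AT5G02760, AT5G61590, BR6OX2, AT3G22183 and AT5G57760 were lower, at -3.79 to -4.65. The wound list had a median of 4.32 at 10 min, with 21 of 26 genes at least 2-fold higher, and 0.16 at 12 h. At 1 h the JAZ, jasmonate biosynthesis and jasmonate response medians were 5.43, 4.93 and 4.56, with 11 of 12, 12 of 15 and 17 of 19 genes at least 2-fold higher. JAZ10 was 1.70 TPM at t0 and 311 TPM at 1 h, LOX2 (AT3G45140) 639 and 3945 TPM, and VSP2 (AT5G24770) 43.8 TPM at t0 and 906 TPM at 4 h. Each of these medians except the 12 h wound median (percentile 90.4) was at percentile 100 among 10000 random lists of matched expression. Genes of those lists were drawn one by one, so for lists whose genes vary together the percentile does not measure chance. Every WT change also rests on the same single t0 library.

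Auxin and tryptophan biosynthesis genes had a WT median of 1.75 at 1 h, with 9 of 14 at least 2-fold higher, and ASA1 (AT5G05730) was 25.03 TPM at t0 and 97.7 TPM at 1 h. At 1 h the median was 1.59 for salicylic acid genes, 1.3 for heat shock genes and 0.73 for ethylene genes, and at 30 min it was 1.29 for abscisic acid genes and -1.15 for SPL genes (percentiles 100, 99.98, 99.35, 100 and 0.05). Touch genes were at 3.25 at 10 min and -3.13 at 12 h. Photosynthesis genes were at 0.37 at 10 min (percentile 100), -0.97 at 1 h, 0.18 at 4 h and -0.50 at 12 h, and ribosome biogenesis genes at 1.75 at 4 h with 10 of 12 at least 2-fold higher and at -0.63 at 12 h. At 12 h the anthocyanin median was 6.68 with 12 of 12 genes at least 2-fold higher, the glucosinolate median 1.48 with 12 of 17, the trichome median 1.28, and the starvation median -2.20. Cell cycle genes were at -0.46 at 4 h (percentile 0.18). Evening clock genes were at -1.25 at 1 h and 1.23 at 4 h, and morning clock genes at -0.12 and 1.92. Auxin response genes were at 0.018 at 30 min, 0.405 at 1 h, 0.90 in the library labelled WT 2 h, 0.286 at 4 h and 0.814 at 12 h. The root founder (0.36 at 12 h), guard cell, epidermis (-0.69 at 2 h), vascular (0.31 at 12 h) and reference lists stayed within the central 95% of the random lists at every time, while 101 of the 182 list values lay outside that range.

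At 12 h in WT GBSS1, F3H, GPT2, CSLA01, PAP1 and AT4G12495 were higher by 7.79 to 9.25, and GASA6, AT2G33830, AT5G03350, EXPA8, LURP1 and AT5G55450 were lower, at -5.54 to -9.18. The library labelled WT 2 h had similar extremes: GBSS1, F3H, GPT2, PAP2, AT4G12495 and EARLI1 were higher by 8.02 to 9.41, and GASA6, AT5G03350, AT2G33830, EXPA8, PCC1 and AT3G15450 were lower, at -5.39 to -9.18. Its anthocyanin list mean was 8.52, against 3.56 in WT at 4 h and 8.22 in WT at 12 h. In the spline test of the 8 WT libraries limma called 0 of 18906 genes, with 3458 at an unadjusted p below 0.05. Without the library labelled WT 2 h 801 genes were called, without the WT 1 h library 1 gene, and with a pseudocount of 0.1 102 genes.

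**Figure D3:**
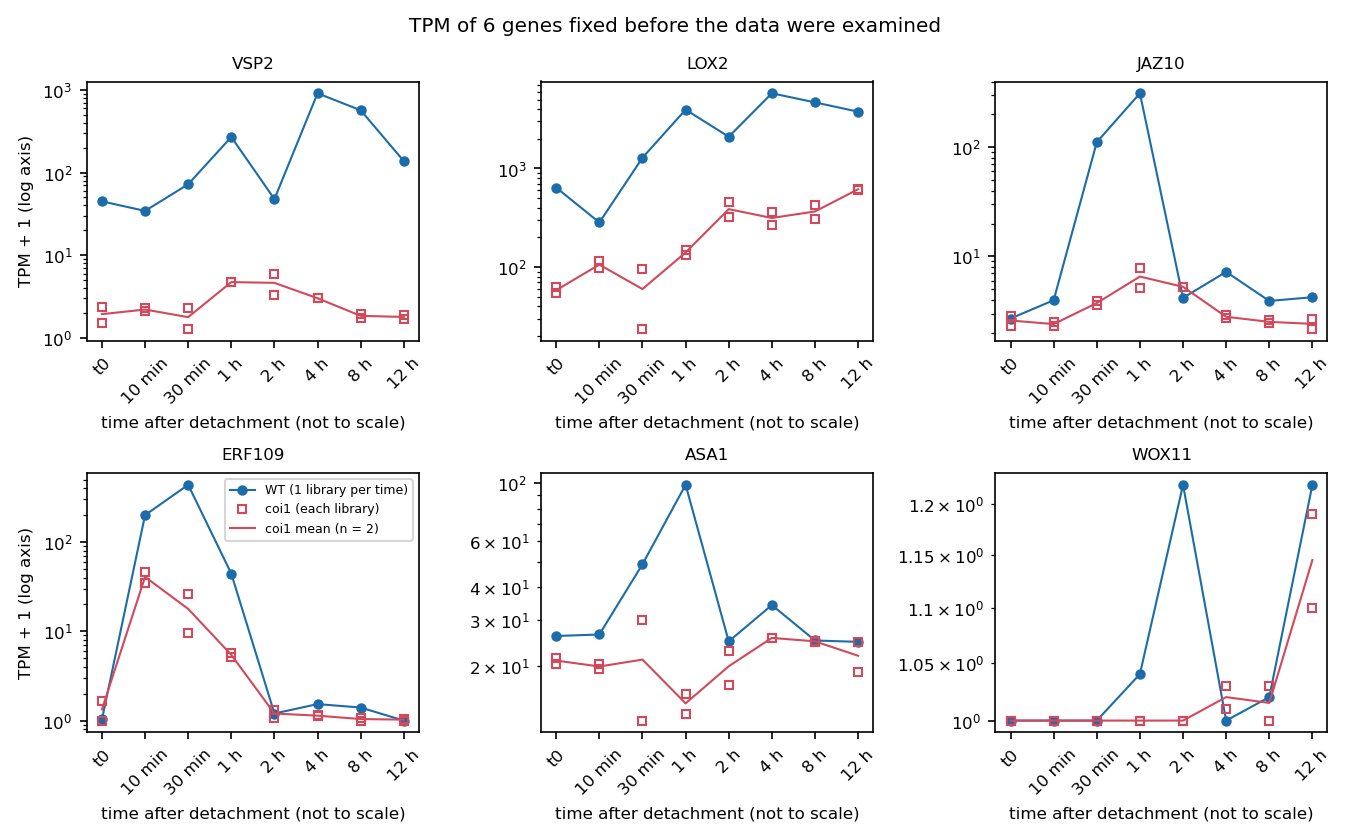
TPM + 1 (y axis, log scale) of VSP2, LOX2, JAZ10, ERF109, ASA1 and WOX11 against time after detachment (x axis, not to scale) in WT (filled circles, 1 library per time) and coi1 (open squares, each library; line, mean of 2). JAZ10 is at 311 TPM in WT at 1 h, and WOX11 is at most 0.22 TPM.

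The genotype comparison asked which transcripts depended on COI1 across the time course. Jasmonate genes were lower in coi1. VSP2 differed by log2 -5.74 ± 0.42 (SE; adjusted p = 3.49e-07), VSP1 (AT5G24780) by -5.42 ± 0.53, the lectin gene AT1G52000 by -5.03, the myrosinase-binding protein gene MBP1 (AT1G52040) by -4.89 ± 0.28 (adjusted p = 1.67e-08) and the glucosidase gene BGLU18 (AT1G52400) by -4.86. AT14A, TSA1 (AT1G52410), CSLA10 (AT1G24070) and AT4G17470 followed at -3.88 to -4.67. AT14A was alike at t0, at 66.1 TPM in WT and 62.4 TPM in coi1, and parted later (251 and 1.36 TPM at 12 h). Its -4.67 is therefore not a constant difference between the genotypes. LOX2 differed by -3.43 ± 0.32. In the jasmonate biosynthesis list 9 of 15 genes were lower and none higher, in the JAZ list 11 of 12 and none, and in the jasmonate response list 13 of 19 and none; adjusted over the list alone the lower counts were 14, 12 and 17. Their medians were -1.42, -1.79 and -1.95, each list mean was lower in coi1 at 8 of 8 times, and the response list ranged from -0.83 at t0 to -4.37 at 1 h. The camera adjusted p was 1.8e-09, 4.12e-09 and 3.56e-12 (0.255, 0.206 and 0.123 with an estimated correlation), and an exact two-sided sign-flip test over the 8 times gave p = 0.0078 for each, the smallest it can give (adjusted p = 0.0339).

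Glucosinolate genes were lower in coi1 already at t0, by -1.92. Of 17, 15 were lower and none higher, or 16 adjusted over the list alone, and the list was lower at 8 of 8 times (median -1.36, adjusted p = 1.82e-17, or 0.087 with an estimated correlation; exact sign-flip p = 0.0078, adjusted 0.0339). BCAT4 differed by -3.38, CYP79F1 by -2.73, MAM1 by -2.54 and the myrosinase gene TGG2 by -1.24 ± 0.09 (adjusted p = 3.49e-07). Among tryptophan genes CYP79B3, CYP79B2, ASB1 and PAT1 differed by -2.28, -1.99, -1.22 and -1.18. Of the 15 genes in the auxin and tryptophan biosynthesis list 7 were lower, and 2, TAA1 (0.82) and YUC8 (0.90), were higher, or 8 and 4 adjusted over the list alone (median -0.73, camera adjusted p = 0.0993, or 0.0283 after rescaling; lower at 8 of 8 times, exact sign-flip p = 0.0078, adjusted 0.0339). ASA1 differed by -0.73 ± 0.23 (adjusted p = 0.0506) and ERF109 by -1.33 ± 0.43 (adjusted p = 0.0526), both not past the threshold. Of the auxin response genes 6 of 17 were higher and none lower, or 8 and 1 adjusted over the list alone. ACS4 (1.39), IAA19 (1.17), IAA29 (1.06) and IAA3 (1.02) were among the higher genes. The list median was 0.41 (camera adjusted p = 1.73e-05, or 0.123 with an estimated correlation, and exact sign-flip p = 0.0156, adjusted 0.058). Its mean difference was 0.44 to 0.78 from t0 to 4 h, but 0.03 at 8 h and 0 at 12 h.

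In the flavonoid pathway 5 of 12 genes were lower in coi1 and none higher, or 8 adjusted over the list alone (median -1.47, adjusted p = 0.000289, or 0.494 with an estimated correlation; exact sign-flip p = 0.0234, adjusted 0.0762). At 12 h, with 1 WT library and no test between members, CHS was at 1889 TPM in coi1 and 2931 TPM in WT, F3H at 811 and 1106, FLS1 at 533 and 494, DFR at 14.6 and 475, LDOX at 27.6 and 488, UF3GT at 15.2 and 132 and the regulator TT8 at 2.7 and 17.2. At 8 h CHS was at 762 and 1864 TPM and F3H at 198 and 657. Over all times DFR differed by -3.13 ± 0.81 (adjusted p = 0.0202), LDOX by -2.84 (adjusted p = 0.0252) and UF3GT by -2.53. PAP1 differed by -1.68, and TTG2, a trichome marker, by -1.71 ± 0.38 (adjusted p = 0.00969). Without the 2 h time, 2 of the 12 genes were lower and the list's median was -0.996 (adjusted p = 0.00259).

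Of the genes higher in coi1, MRD1 (AT1G53480) differed by 4.36 ± 0.31 (adjusted p = 3.49e-07), CIPK20 (AT5G45820) by 3.05 ± 0.68, GolS3 (AT1G09350) by 2.95, BBX28 (AT4G27310) by 2.62, AT1G62510 by 2.54, and LHCB1.1, LHCB2.1, LHCB2.2, AT5G06980 (LNK4) and AT3G12320 (LNK3) by 2.29 to 2.69. Of these 10 MRD1 alone was called without exception in the alternatives run. The calls of LHCB1.1, LHCB2.1, LHCB2.2, AT5G06980 and AT3G12320 ended without the WT 30 min, WT 1 h or WT 2 h library. In the photosynthesis list 10 of 20 genes were higher and RBCS2B was lower (-0.59), or 14 and 1 adjusted over the list alone (median 0.48, adjusted p = 6.47e-06, or 0.344), and 3 of 8 morning clock genes were higher, or 5 adjusted over the list alone (median 1.85, adjusted p = 0.000808, or 0.372). Their exact sign-flip p was 0.0703 and 0.0547 (adjusted 0.131 and 0.109). The coi1 libraries at 30 min to 4 h held more morning clock transcript than the WT libraries of the same times, and these genes follow the time of day; GI, an evening gene, was also higher (1.63). Without the 2 h time no photosynthesis gene was called, while the list kept its call (median 0.37, adjusted p = 0.000149). Reads shared between near-identical LHCB, RBCS, AOC, CBF and VSP paralogs leave the division among their members uncertain.

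**Figure D4:**
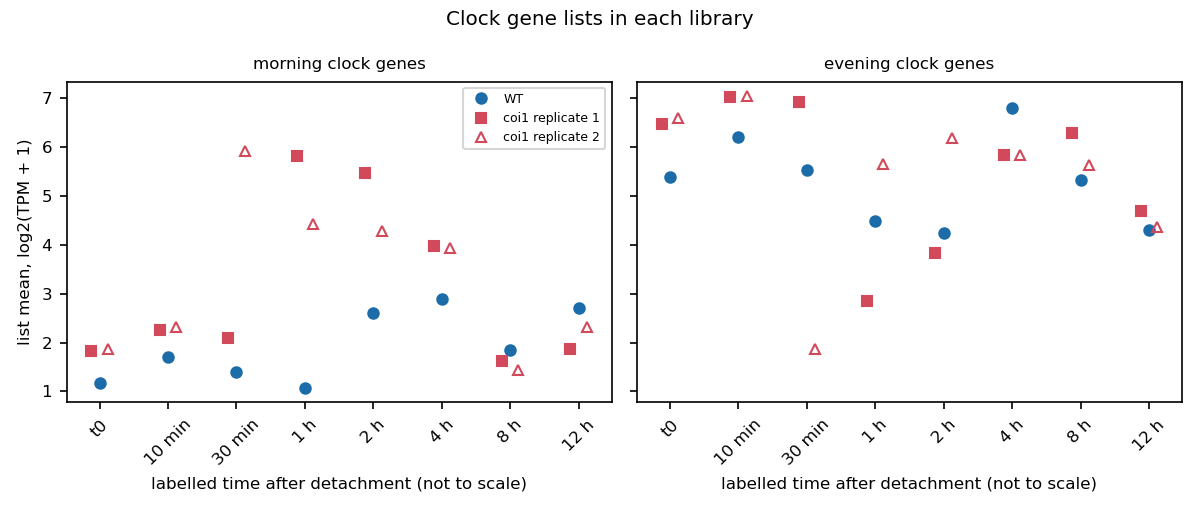
Mean log2(TPM + 1) of 8 morning and 8 evening clock genes (y axis) in each library against labelled time after detachment (x axis, not to scale). The coi1 libraries at 30 min lie at 2.09 (replicate 1) and 5.92 (replicate 2) for morning genes, and WT at 1 h lies at 1.08.

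Vascular markers were lower in 4 of 10 cases by either adjustment, SWEET12 by -1.66 and APL by -0.58 (median -0.24, adjusted p = 0.00629, or 0.324 with an estimated correlation; lower at 8 of 8 times, exact sign-flip p = 0.0078, adjusted 0.0339; 2 lower after rescaling). ATML1, 1 of 3 epidermis markers, was higher by 0.65, the same adjusted over the list alone (list camera adjusted p = 0.0226, or 0.324 with an estimated correlation). For the epidermis list the camera adjusted p was 0.086 without the 2 h time, 0.0758 with replicate number as a block and 0.0563 after rescaling. No ribosome biogenesis gene of 12 was called by either adjustment (median 0.18, camera adjusted p = 0.0146, or 0.63 with an estimated correlation). For that list it was 0.19 without the 2 h time and 0.0521 with the block. The auxin and tryptophan biosynthesis list, described above, was not called (camera adjusted p = 0.0993). The other lists not called were wound (2 higher, 3 lower of 26, with CBF3 1.46 and RAP2.6 -1.86, adjusted p = 0.474), touch (0 of 3), SPL (SPL9 0.85, SPL11 -0.99), ethylene (ACS8 0.71), root founder (NAC1 0.33), salicylic acid (ICS1 0.58, EDS5 -1.05), starvation (SEN1 1.26, BCAT2 -0.68), cell cycle (CYCD3;2 0.54), heat shock (HSP18.2 0.47), trichome (TTG2 and GL2 lower), evening clock (GI), reference (TIP41L -0.25), abscisic acid (0 of 15) and guard cell (0 of 5), with adjusted p from 0.199 to 0.896. Adjusted over the list alone the higher and lower counts were 2 and 4 for wound, 1 and 1 for SPL and salicylic acid, 2 and 1 for ethylene and starvation, 1 and 2 for root founder, heat shock and reference, 1 and 0 for cell cycle and evening clock, 0 and 2 for trichome, and 0 for touch, abscisic acid and guard cell. In the abscisic acid, salicylic acid, heat shock, guard cell and evening clock lists the median lay below 0 and the test pointed up.

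With limma 2476 of 19757 genes differed by genotype, 764 higher and 1712 lower, of which 142 and 324 by at least 2-fold. The share of higher genes was 30.9%, and 45% after rescaling. The count was 1365, 1350 and 1391 without the WT 30 min, WT 1 h and WT 2 h library, 1168 without the 2 h time, 962 without the 2 h and 30 min times, 927 with replicate number as a block, 229 with coi1 replicate number 1 alone and 4401 with the 16 group means. The 11 list calls of 26 all ended with an estimated correlation, and 9 remained past the threshold without the 2 h time.

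The test of the time course itself asked where coi1 and WT diverged in shape. PYK10 (AT3G09260) was 8.97 TPM at t0 and 151 TPM at 4 h in WT, and 20.7 and 7.74 TPM in coi1. PBP1 (AT3G16420) reached 639 TPM in WT at 4 h against 61.6 TPM in coi1, JAL23 (AT2G39330) 29.2 against 0.16 TPM and MBP2 (AT1G52030) 44.0 against 0.20 TPM, and MEB1 (AT4G27860) was 14.9 against 1.33 TPM at 12 h. JAZ7 (AT2G34600) and JAZ8 (AT1G30135) were 200 and 69.3 TPM in WT at 30 min against 0.94 and 1.14 TPM, and CSLA10 was 287 against 51.4 TPM at 12 h. SEN1 (AT4G35770), a starvation gene, was 0.76 TPM in WT at 30 min against 15.5 TPM. With limma 40 genes passed, and the adjusted p was 2.19e-06 for PYK10, 0.00809 for JAZ7 and 0.0131 for SEN1. The count was 186 without the WT t0 library, 110, 12, 122 and 110 without the WT 10 min, 30 min, 2 h and 4 h libraries, 111 without coi1 30 min replicate 1, and 19 to 24 without coi1 t0 replicate 1 (23), 10 min replicate 1 (24), 10 min replicate 2 (23), 1 h replicate 1 (23), 1 h replicate 2 (24), 2 h replicate 1 (22), 4 h replicate 2 (19) or 8 h replicate 1 (22). PYK10 was called in all of these fits, and JAZ7 and SEN1 were not called without the WT 30 min library. Other settings gave 1299 genes with time as a factor, 11 with a pseudocount of 0.1, 10 with the shorter spline, 123 with no filter, 15 with a filter of 5 TPM, 24 with replicate number as a block and 65 without the 2 h time. With coi1 replicate number 1 alone 1 gene was called, and PYK10 was not (adjusted p = 0.0552).

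Across genes, WT and coi1 changes from t0 were most alike late. Every coi1 change used the t0 replicates, and the 30 min change the 30 min replicates, which differed as described below. What these libraries did to the correlations was not tested. Pearson's r across 19757 genes, which are not independent replicates, was 0.581 at 10 min, 0.464 at 30 min, 0.52 at 1 h, 0.497 at 2 h, 0.681 at 4 h, 0.716 at 8 h and 0.79 at 12 h. The library labelled WT 2 h had r = 0.802 with the coi1 change at 12 h.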

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

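The tests of the 3 sets of libraries below were chosen after the result was seen; the counts of other splits were planned before.

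The test for a different time course in coi1 and WT called 40 genes, and the 20 named among them differed between the groups by this interaction test. The adjusted p was 2.191e-06 for PYK10, 0.008086 for JAZ7, 0.01048 for AT1G68250, 0.01305 for each of JAL23, AT5G03204, SEN1 and MBP2, 0.015 for MEB1, 0.02342 for CSLA10, 0.02455 for AT3G24100, 0.02576 for MRD1, 0.02586 for UMAMIT10, 0.03683 for AT5G14450, 0.0378 for each of AT3G22160 (JAV1), JAZ8, VSP1 and AT2G42760, 0.04117 for PBP1, and 0.04156 for AT1G25500 and RTFL16. Transcripts of AT1G68250 and AT5G03204 reached 14.3 and 12.7 TPM in WT between 30 min and 1 h and at most 0.36 and 0.18 TPM in coi1 group means. UMAMIT10, a transporter gene, was 14.7 TPM in WT at 4 h against 3.08 TPM, and RTFL16, a small-peptide gene, was 2.38 TPM in WT at 30 min against 42.9 TPM. AT3G24100 was 44.5 against 105 TPM, AT2G42760 was 70.0 against 3.97 TPM and AT1G25500 was 21.9 against 1.06 TPM, all at 30 min, and AT5G14450 was 10.9 against 25.2 TPM at 1 h.

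Other splits put 1 library of each time in the smaller arm. In 1 of 100 such splits, the real one, the genotype count reached 2476, and the highest of the others was 964, in a split that kept 6 of the WT libraries together. For the time-course difference 2 of 100 splits, the real one among them, gave at least 40 genes, and the highest of the others was 46. Both shares were below the 0.05 set beforehand. For genotype no other drawn split reached the real count. For the time-course difference another split exceeded it, so chance was not excluded there. Such splits show only that the WT libraries differed from coi1 as a set. Separate tables or a difference in time of day would give the same result. No group held enough libraries for a test of single outlying samples.

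The library labelled WT 2 h lay closer to the late libraries than to its neighbours in time. Over 11380 genes that varied across the coi1 times it differed from WT 12 h by a root mean square of 0.26 log2 units, less than the median of 0.334 between coi1 replicates, and from WT 1 h and 4 h by 1.291 and 0.963. A harvest at another time of day stays open. The anthocyanin list mean was 8.52, and 17 other libraries of 4 h or less reached 3.56. This was above their highest by more than their SD of 0.79, the limit set for arguing against it. The value rests on 1 library, and those in a marked morning clock state were all coi1. Outside 2 h, coi1 minus WT in this list ranged from -0.75 to 0.20 up to 4 h. It was -3.42 at 8 h and -1.99 at 12 h. With no other WT library in that state, the test cannot decide for a WT library. The morning and evening clock means of the library labelled WT 2 h were 2.61 and 4.24, near 2.71 and 4.31 in WT 12 h. A wrong time label stays open, since the distance of 0.26 from WT 12 h measures again the closeness that raised the question. A transient state of WT leaves at 2 h stays open, as 1 WT library of that time was used here.

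The coi1 libraries at 30 min differed from each other more than any other pair. A few genes taking most of the TPM was argued against, since after rescaling the pair still differed by 1.027, against at most 0.684 in other pairs. Clock genes parted more than all 10000 matched random lists (percentile 100), with morning genes at 4.86 and evening genes at -4.59 for replicate 2 minus replicate 1, so harvest at different times of day is a candidate explanation. CCA1 was 154 against 0.7 TPM and GI 5.5 against 53.7 TPM. A wrong label stays open. With clock genes left out, the nearest coi1 library of another time to replicate 2 was 1 h replicate 1 at 0.731. This was above the highest distance between other replicates (0.692) by less than their SD of 0.123. That highest pair was the t0 pair, itself flagged below, so this limit cannot decide.

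The library coi1 t0 replicate 1 held touch and wound transcripts at levels of detached leaves. TCH4 was 578.5 TPM in replicate 1 and 4.4 TPM in replicate 2, and TCH2 was 500.8 and 31.0 TPM. The touch and wound lists were higher by medians of 6.26 and 2.95, at percentile 100 of matched random lists. These values are the ones that raised the question, so a delay or touch before freezing stays open. A wrong label stays open too. The nearest coi1 library of another time, coi1 10 min replicate 1, was at 0.595, above the median of 0.406 among other replicate pairs. The highest of these pairs, at 1.039, was the 30 min pair flagged above, so that limit cannot decide. Replicate pairs of times other than t0 and 30 min differed by 0.319 to 0.501. Over both genotypes the most correlated library was WT 10 min (r = 0.965). No biological explanation was tested for either coi1 pair, as the design gives none within a group.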

How the results depend on the processing

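The alternatives without the 2 h time, without the 2 h and 30 min times, with the shorter spline lacking the library labelled WT 2 h, and the list tests with libraries left out were chosen after seeing the data. No named call with a direction reversed it. The wound list from 2 h to 12 h and the touch list did turn with the coi1 t0 library left out (touch at 10 min from 2.06 to -1.06), and the share of higher genes at 30 min went from 29.9% to 61.8% after rescaling. In comparisons of the 76 named calls with alternatives 1442 kept the call and 331 lost it, and 57 of the 76 were kept with a pseudocount of 0.1. Genes outside the threshold were not followed here.

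In coi1 rescaling gave 1167 genes at 30 min. Fits of only the 4 libraries compared gave 0 genes at 10 min and 0 at 30 min, 2967 at 1 h, 4560 at 4 h and 1595 at 8 h. With one library left out the counts ranged from 26 to 372 at 10 min, 140 to 7894 at 30 min, 2965 to 4994 at 1 h, 2221 to 3478 at 2 h, 698 to 1948 at 4 h, 1467 to 2315 at 8 h and 1931 to 3126 at 12 h. The cause of these differences was not tested. The other pseudocount, both filters and moderation without trend kept the coi1 counts within 1.5-fold.

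In WT the count of 0 became 102 with a pseudocount of 0.1, and 223 with the shorter spline without the library labelled WT 2 h. Leaving out single libraries gave 0 to 801, and the cause was not tested.

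The genotype count of 2476 became 229 with coi1 replicate number 1 alone (fewer samples), 4401 with the 16 group means, 1168 without the 2 h time and 962 without the 2 h and 30 min times. It ranged from 1350 to 3089 with one library left out, and from 2107 to 2471 with the other pseudocount, either filter, rescaling or moderation without trend. The time-course count of 40 became 11 with a pseudocount of 0.1, 123 with no filter, 15 with a filter of 5 TPM, 1 with coi1 replicate number 1 alone, 10 with the shorter spline, 1299 with time as a factor and 65 without the 2 h time. It ranged from 12 to 186 with one library left out, and was 33 after rescaling, 41 without trend and 57 without the 2 h and 30 min times. Apart from the fits with fewer samples or genes, the cause was not tested.

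With replicate number as a block the genotype count was 927 and the time-course count 24, and the coi1 counts stayed within 1.5-fold. Replicate numbers did not pair the libraries in the same way at all times. Of 28 pairs of times, 7 had a correlation above 0.1 between replicate differences, in a range from -0.31 to 0.50. Some times did share a difference. The morning clock median of replicate 2 minus replicate 1 was -1.37 at 1 h and -1.29 at 2 h, but 4.86 at 30 min.

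Of the lists, 59 calls at coi1 times and 11 by genotype became 0 and 0 with an estimated correlation, which widens the spread allowed for lists whose genes vary together. Calls at coi1 times ranged from 52 to 76 with one t0 or 30 min library left out. By genotype 9 lists were called with the block and 9 without the 2 h time. In WT 104 list values instead of 101 lay outside the middle range with a pseudocount of 0.1. Depth is unknown in TPM, so what depth limits could not be stated.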

Other observations

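CSLA01, a cellulose synthase-like gene, was 0.34 TPM at t0, 98.7 TPM at 1 h and 366 TPM at 12 h in WT, and 0.08, 0.91 and 37.1 TPM in coi1, where it rose by log2 5.06 at 12 h. Its genotype difference was -3.41 ± 0.65 (adjusted p = 0.0035). CSLA10 was 4.69, 126 and 287 TPM in WT and 0.79, 0.36 and 51.4 TPM in coi1.

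MRD1 and AT14A, which the rule names, were looked at library by library after their values were seen. MRD1 was 10.7 TPM in the WT t0 library, 0 to 0.17 TPM in the 7 other WT libraries and 20.4 to 45.7 TPM in the 16 coi1 libraries. AT14A was 65.4 to 251 TPM in the 8 WT libraries. In coi1 it was 20.5 to 75.6 TPM in the 5 libraries of t0, 10 min and 30 min replicate 1, and 0.15 to 2.80 TPM in the other 11.

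The clock genes also parted between coi1 replicates at 1 h and 2 h. The morning and evening list means were 5.82 and 2.86 in 1 h replicate 1, 4.42 and 5.66 in 1 h replicate 2, 5.47 and 3.83 in 2 h replicate 1, and 4.28 and 6.19 in 2 h replicate 2. In WT they were 1.08 and 4.48 at 1 h. LHY was 102 TPM in coi1 30 min replicate 2 and 0.3 TPM in replicate 1, and FKF1 was 0 and 54.7 TPM. Across whole transcriptomes the replicates correlated at r = 0.885 across genes at 30 min, 0.947 at t0 and 0.971 or more at the other times.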
